A study of Arabidopsis thaliana with 24 samples.

How the data were processed

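The samples were whole seedlings of Arabidopsis thaliana, ecotype Columbia-0, aged 11 days and grown, per the labels, in liquid MS medium with 1% sucrose at 23 °C under 16 h of light and 8 h of dark. Methyl jasmonate in DMSO (50 µM) or DMSO alone was added for 1 h. Wild type and lines with ProMYC2:MYC2-SRDX or ProJAM1:JAM1-SRDX gave 3 genotypes by 2 treatments with 4 replicates each. Per the labels total RNA was isolated with the Plant RNeasy Mini kit, and 200 ng was labelled with Cy3 by the Low Input Quick Amp Labeling kit. The labels say that many seedlings were harvested but not that replicates came from separate cultures, so the p-values measure only the spread between these samples.

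The authors deposited 1 scanner file per array, written per the file headers by Agilent Feature Extraction 9.1.3.1, and a series matrix. The processed signal of the scanner files is an intensity, background-subtracted by that program per the file headers, and the flags for background, saturation and outliers are of the kind other. The series matrix is an intensity on a linear scale with no centring by gene: each column was the deposited processed signal over 1 constant per group (1280.8 to 1502.7), with column medians of 0.338 to 0.519. How the authors chose those constants is not stated, and 0 of its columns were left unused. Each array held 45220 spots, 43803 of them not controls, for 43603 distinct probes. Of these 36022 carried a RefSeq identifier, 34185 were matched through the reference table to 25347 loci, and 9418 were matched to none. No spot was saturated (0 in total), and 60 spots marked as outliers by the scanner software were left out. The correlation between replicates was at least 0.9887 in every group.

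From the deposited files, log2 of the processed signal minus each array's 75th percentile was computed here. Spots of 1 probe were averaged, each locus was represented by the probe with the highest mean over the 24 arrays, and probes well above background on all arrays of at least 1 group were kept, which left 28201 probes and 20397 genes. Of 6028 loci with several probes 0 to 38 per comparison had probes called in both directions. All 24 arrays entered 1 fit of 6 group means in limma 3.58.1 with statmod 1.5.0 under R 4.3.3, with empirical Bayes moderation. Each of the 12 contrasts was adjusted by Benjamini-Hochberg over all genes, and a gene passed at an adjusted p under 0.05. A difference of JA responses was the JA minus mock change of 1 genotype minus that of another. Genes were named by a rule fixed before the data were examined: MYC2, JAM1, JAM2 and JAM3, the 8 largest rises and 8 largest falls past the test whose groups did not overlap, and from each list up to 4 members past the test and 2 that did not pass. From the genes that rule gave, those in the text were picked for their known function, and gene calls that ended when 1 array was left out were passed over in the results.

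The gene lists were fixed before the data were examined, 26 lists of 295 genes, 292 of them with a probe: JA biosynthesis, JA catabolism, JAZ repressors, JA core signalling, JA-associated transcription factors, MYC branch defence and wound, ERF branch defence, flavonoid and anthocyanin enzymes, anthocyanin and trichome regulators, indole glucosinolate, aliphatic glucosinolate, tryptophan biosynthesis, sulfate, glutathione and ascorbate, early touch and general stress, salicylate, abscisic acid, early auxin, photosynthesis and chlorophyll, root markers, flower and seed markers, circadian clock, cell division, heat shock, low oxygen, iron deficiency and reference genes. The 25 lists with at least 5 measured genes were tested with limma camera at its preset correlation of 0.01, adjusted over the 25 lists of a contrast, and again with the correlation estimated per list.

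The share of the JA response kept by each line was computed with genes chosen on 2 mock and 2 JA arrays of wild type (adjusted p under 0.05 and at least 2-fold higher) and measured on the other 4, over 6 choices. Because both lines were set against the same wild-type arrays, the overlap of their calls was also computed with the wild-type arrays split between them (6 splits) and in 100 simulations with no effect. The test was also tested on simulated data: of 50 changed genes per size, 76, 90, 96 and 96% were recovered at 1.5, 2, 3 and 4-fold in the JA response of wild type with 8 false calls, and 74, 88, 92 and 94% in the difference of responses of JAM1-SRDX with 10. A simulated list shift was found with 0 of 24 other lists called, and a true share of 50% was measured as 49.9 and 49.6%. The simulated genes varied independently and held no slide effect, so these values do not show how often correlated genes or slides give false calls.

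Per the file headers the arrays came from 7 slides scanned on 2 days. Wild-type mock, wild-type JA and MYC2-SRDX mock each filled 1 slide, and 1 slide, read on the second day, held 2 arrays of MYC2-SRDX JA, 1 of JAM1-SRDX mock and 1 of JAM1-SRDX JA. The other arrays of these 3 groups lay on 1 slide per group. Slide was fitted as a fixed block where a slide held both groups compared, and as a random block elsewhere (correlation within a slide 0.279). The labels do not pair replicates. The residuals of same-numbered arrays were checked: every pair correlated above 0.1 only between mock and JA of MYC2-SRDX (0.12 to 0.40, mean 0.26) and of JAM1-SRDX (0.27 to 0.46, mean 0.38), where 3 of 4 arrays matched best with their own number. Other settings tried were quantile normalization, other filters on dim probes, the mean of all probes of a locus, moderation with trend and robust, the scan day as a block, the series matrix values, only the arrays compared, and leaving out each array. The design named normexp background correction with the gMeanSignal column; that column is absent from the files, so gMedianSignal with gBGMedianSignal and an offset of 50 was used.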

Results

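RNA of whole 11-day-old Arabidopsis seedlings was read on 24 single-colour arrays, 4 for each of 6 groups. The groups were wild type, MYC2-SRDX and JAM1-SRDX, each given solvent (mock) or 50 µM methyl jasmonate (JA) for 1 h. MYC2 and JAM1 are related bHLH transcription factors of jasmonate signalling, and SRDX is a short motif that turns a factor fused to it into a dominant repressor. Per the labels each fusion was driven by the promoter of its own factor. The 75th percentile of the processed signal ran from 2708.9 to 3692.4 over the arrays, and 71.4 to 81.1% of the probes were well above background. In all, 20397 genes were tested, with a median residual SD of 0.108 on the log2 scale. With 4 arrays per group the median SE of a difference was 0.0754, and the number of arrays limits how small a change could be seen. The questions were what JA changed in each genotype, how each line differed from wild type with and without JA, and whether the lines answered JA as wild type did. Values are log2 differences ± SE from limma with 4 arrays per group, levels are mean log2 ± SD relative to each array's 75th percentile and p-values are adjusted over all genes or lists tested. In comparisons of 2 groups, where a gene was not well above background on any array of a group, its fold is given as at least a value. That value sets the bright group's mean against the dim group's mean of, on each array, the higher of the lowest signal among probes well above background and the dim probe's own signal. In these comparisons, where only some arrays of a group were well above background, their number is given. The size of such a difference rests in part on background signal.

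The probes of the 2 fused genes separated the genotypes. MYC2 (AT1G32640) stood at 1.34 ± 0.24 in wild-type mock, 3.82 ± 0.08 in MYC2-SRDX mock and 0.75 ± 0.21 in JAM1-SRDX mock. JAM1 (AT2G46510) stood at 0.88 ± 0.16, 0.47 ± 0.06 and 3.29 ± 0.42 in the same 3 groups. After JA the MYC2 probe reached 3.95 ± 0.04 in wild type, 4.94 ± 0.12 in MYC2-SRDX and 3.08 ± 0.17 in JAM1-SRDX, and the JAM1 probe 2.88 ± 0.06, 2.22 ± 0.01 and 4.88 ± 0.33. A probe of SUP, the floral regulator whose repression domain was the model for the SRDX motif, was not well above background on any wild-type array. The same probe read 3.18 ± 0.06 in MYC2-SRDX mock and 2.67 ± 0.45 in JAM1-SRDX mock. No probe positions were at hand, so the share of each signal that came from the transgene is not known.

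**Figure D1:**
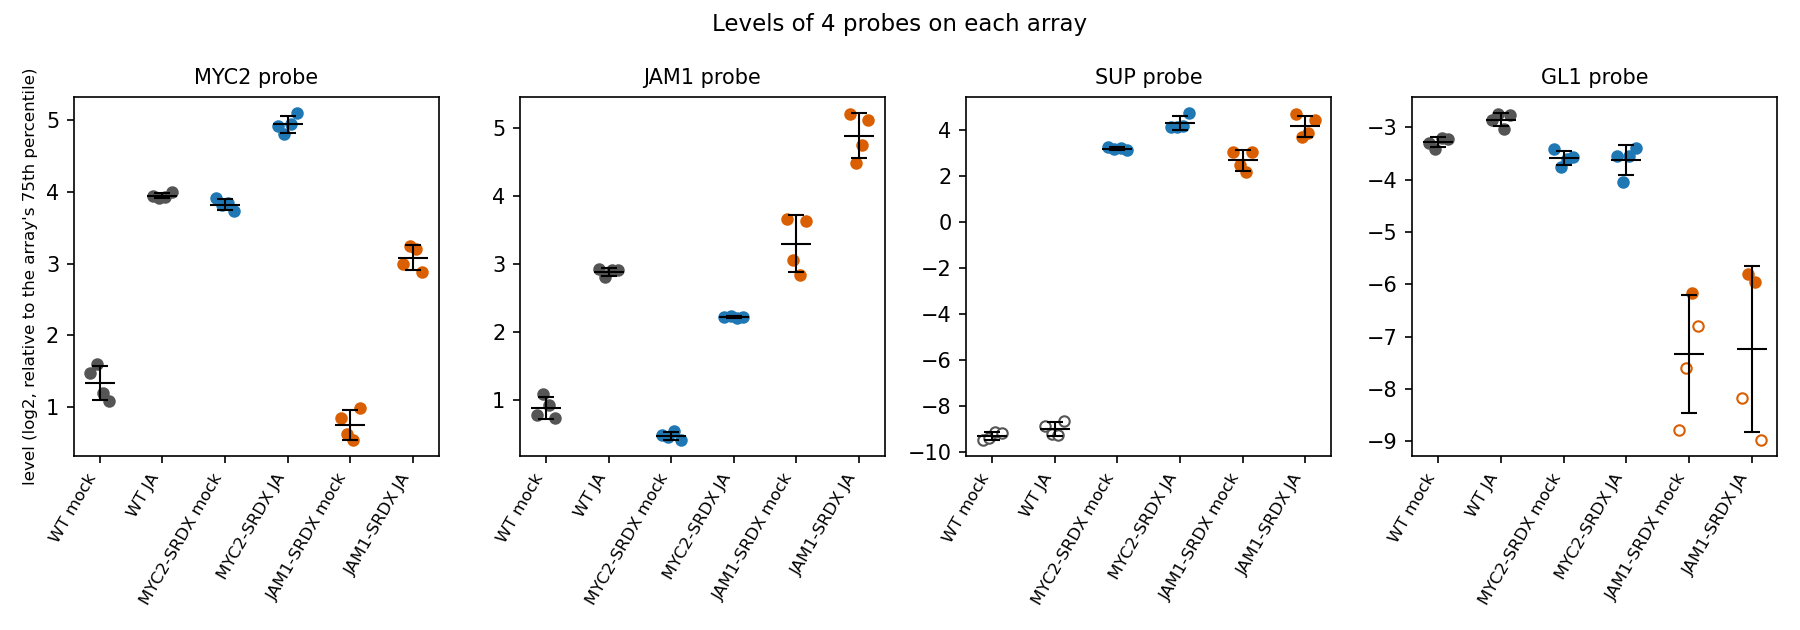
Levels of the MYC2, JAM1, SUP and GL1 probes on each of the 24 arrays, in log2 relative to the array's 75th percentile; points are arrays (open where not well above background), and bars are group means ± SD of 4 arrays. In mock seedlings the MYC2 probe was 2.48 higher in MYC2-SRDX and the JAM1 probe 2.41 higher in JAM1-SRDX than in wild type, while the GL1 probe was well above background on 3 of the 8 JAM1-SRDX arrays.

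In wild type, 1 h of JA raised genes for the making, breakdown and perception of jasmonate. CYP94B1, a cytochrome P450 that oxidises the active jasmonate conjugate, rose 78.3-fold (6.29 ± 0.18, adjusted p = 1.91e-15). MYC2 rose by 2.61 ± 0.11 (adjusted p = 1.31e-13), JAM1 by 2 ± 0.15 (adjusted p = 1.68e-09) and JAM2, a close relative of JAM1, by 0.53 ± 0.09 (adjusted p = 0.000106). JAM3, the third member of that clade, did not pass (-0.09 ± 0.05, adjusted p = 0.191). MYB21, a MYB factor of stamen growth, rose at least 12.8-fold from a level not well above background on any mock array (adjusted p = 2.77e-11). JAZ13, a jasmonate repressor well above background on 2 of the 4 mock arrays, rose by 5.90 ± 0.41 (adjusted p = 2.93e-10). AT5G57760, a gene without a symbol in the reference, fell by 2.60 ± 0.20 (adjusted p = 1.11e-09). ZAT7, a zinc-finger factor of stress responses, fell by 2.17 ± 0.42 (adjusted p = 0.000336). In total 2947 genes rose and 4141 fell, with 797 rising and 248 falling at least 2-fold. The groups did not overlap at 7781 of the 20397 genes, where chance gives 2.86% per gene if the arrays are interchangeable. Each of the groups filled its own slide, so a slide difference could add to that count. The total of 7088 became 3506 with the slide as a random block and 3089 after normexp background correction, and with the series matrix values 59.3% of the calls were higher in place of 41.6%.

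All 16 measured genes of JA biosynthesis rose in wild type, also when adjusted over the list alone (camera, adjusted p = 2.69e-18). AOC1, an allene oxide cyclase, rose by 2.72 ± 0.20 (adjusted p = 9e-10), LOX3, a lipoxygenase, by 2.62 ± 0.18 (adjusted p = 3.74e-10). JMT, which methylates jasmonic acid, rose by 2.68 ± 0.14 (adjusted p = 3.15e-12). Of JA catabolism all 9 measured genes rose (9 over the list alone, adjusted p = 1.86e-12), among them CYP94B3 by 4.19 ± 0.18 (adjusted p = 2.31e-13) and the jasmonate oxidase JOX4 by 4.21 ± 0.60 (adjusted p = 1.1e-05). Of the JAZ repressors 11 rose and 1 did not pass (11 over the list alone, adjusted p = 1.86e-12). JAZ10 rose by 3.96 ± 0.25 (adjusted p = 9.65e-11), while JAZ11 stayed at -0.08 ± 0.04 (adjusted p = 0.169). The JA-associated transcription factors rose at all 11 measured genes (11 over the list alone, adjusted p = 6.19e-10), with MYB47 at 3.41 ± 0.21 (adjusted p = 5.56e-11). JA core signalling, which holds MYC2 and its partners, had 6 genes higher, 1 lower and 4 not passed (6 and 1 over the list alone, adjusted p = 0.00274; adjusted p = 0.0673 with an estimated correlation).

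Defence and wound genes of the MYC branch rose at 10 of 11 measured genes in wild type (11 over the list alone, camera adjusted p = 1.86e-12). TPS04, a terpene synthase of volatile defence, rose by 4.97 ± 0.54 (adjusted p = 2.78e-07) and TAT3, an aminotransferase, by 4.45 ± 0.65 (adjusted p = 1.51e-05). NATA1, an acetyltransferase that makes an ornithine defence compound, was 1.85 ± 0.72 higher and did not pass (adjusted p = 0.0532). ERF branch defence had 4 genes higher, 1 lower and 6 not passed (4 and 2 over the list alone), and its camera test did not pass (adjusted p = 0.32). Its median of -0.66 and mean of -0.26 were below 0 while the test leaned upward. ERF1 rose (2.12 ± 0.18, adjusted p = 6.41e-09), while ORA59, another activator of that branch, fell by 0.66 ± 0.11 (adjusted p = 7.99e-05). Indole glucosinolate genes rose at 11 and fell at 2 of 13 (the same over the list alone, adjusted p = 6.19e-10), led by CYP79B3 (2.46 ± 0.11, adjusted p = 1.97e-13) and the regulator MYB34 (2.44 ± 0.10, adjusted p = 8.21e-14). Tryptophan biosynthesis rose at all 7 genes (7 over the list alone, adjusted p = 1.91e-11), with the anthranilate synthase ASA1 at 2.04 ± 0.08 (adjusted p = 9.02e-14). Aliphatic glucosinolate genes rose at 12, fell at 1 and did not pass at 1 (12 and 1 over the list alone, adjusted p = 2.17e-09; adjusted p = 0.056 with an estimated correlation). Sulfate, glutathione and ascorbate genes rose at 7, fell at 2 and did not pass at 5 (9 and 2 over the list alone, adjusted p = 4.93e-05; adjusted p = 0.0728 with an estimated correlation). In that list VTC5, an enzyme of ascorbate synthesis, rose by 2.23 ± 0.08 (adjusted p = 2.23e-14).

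Among pigment genes of wild type, flavonoid and anthocyanin enzymes rose at 7, fell at 1 and did not pass at 6 of 14 (9 and 1 over the list alone, camera adjusted p = 0.0209; adjusted p = 0.377 with an estimated correlation). CHS, the entry enzyme of the pathway, stayed at 0.05 ± 0.08 (adjusted p = 0.633). Anthocyanin and trichome regulators rose at 5 of 10 (5 higher and 2 lower over the list alone, adjusted p = 0.0123; adjusted p = 0.207 with an estimated correlation), with MYB75, an activator of anthocyanin genes, at 2.13 ± 0.23 (adjusted p = 2.66e-07). Heat shock genes rose at 5 of 8 (5 over the list alone, adjusted p = 0.0123; adjusted p = 0.288 with an estimated correlation). The enzyme list was lost after normexp (0.72, adjusted p = 0.0621), and the regulators were lost over probes well above background on all 24 arrays (0.52, adjusted p = 0.216).

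The remaining lists did not pass the camera test in wild type. Higher, lower and not passed genes numbered 4, 7 and 5 for early touch and general stress (4 and 9 over the list alone, adjusted p = 0.218). They were 4, 2 and 6 for abscisic acid (5 and 2 over the list alone, adjusted p = 0.0556), where RD20, a caleosin of drought responses, rose by 2.95 ± 0.23 (adjusted p = 2.57e-09). They were 3, 3 and 4 for salicylate (3 and 3 over the list alone, adjusted p = 0.673), whose median of -0.22 lay below 0 while its mean of 0.49 and the test leaned upward. Early auxin had 2, 3 and 2 (2 and 3 over the list alone, adjusted p = 0.428), circadian clock 1, 4 and 6 (2 and 4, adjusted p = 0.198), and iron deficiency 0, 2 and 8 (0 and 2, adjusted p = 0.221). Root markers had 1, 1 and 9 (0 and 0 over the list alone, adjusted p = 0.353), cell division 1, 0 and 7 (0 and 0, adjusted p = 0.244), and low oxygen 1, 0 and 9 (1 and 0, adjusted p = 0.218). Photosynthesis and chlorophyll had 0 of 12 genes past the test (0 over the list alone, adjusted p = 0.708), and reference genes 0 of 9 (0 over the list alone, adjusted p = 0.218), with UBQ10 at 0.17 ± 0.10 (adjusted p = 0.185). Flower and seed markers had 4 measured genes, too few to test, of which 1 rose (1 over the list alone): SESA1, a seed storage albumin, by 4.19 ± 0.34 (adjusted p = 4.15e-09).

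**Figure D2:**
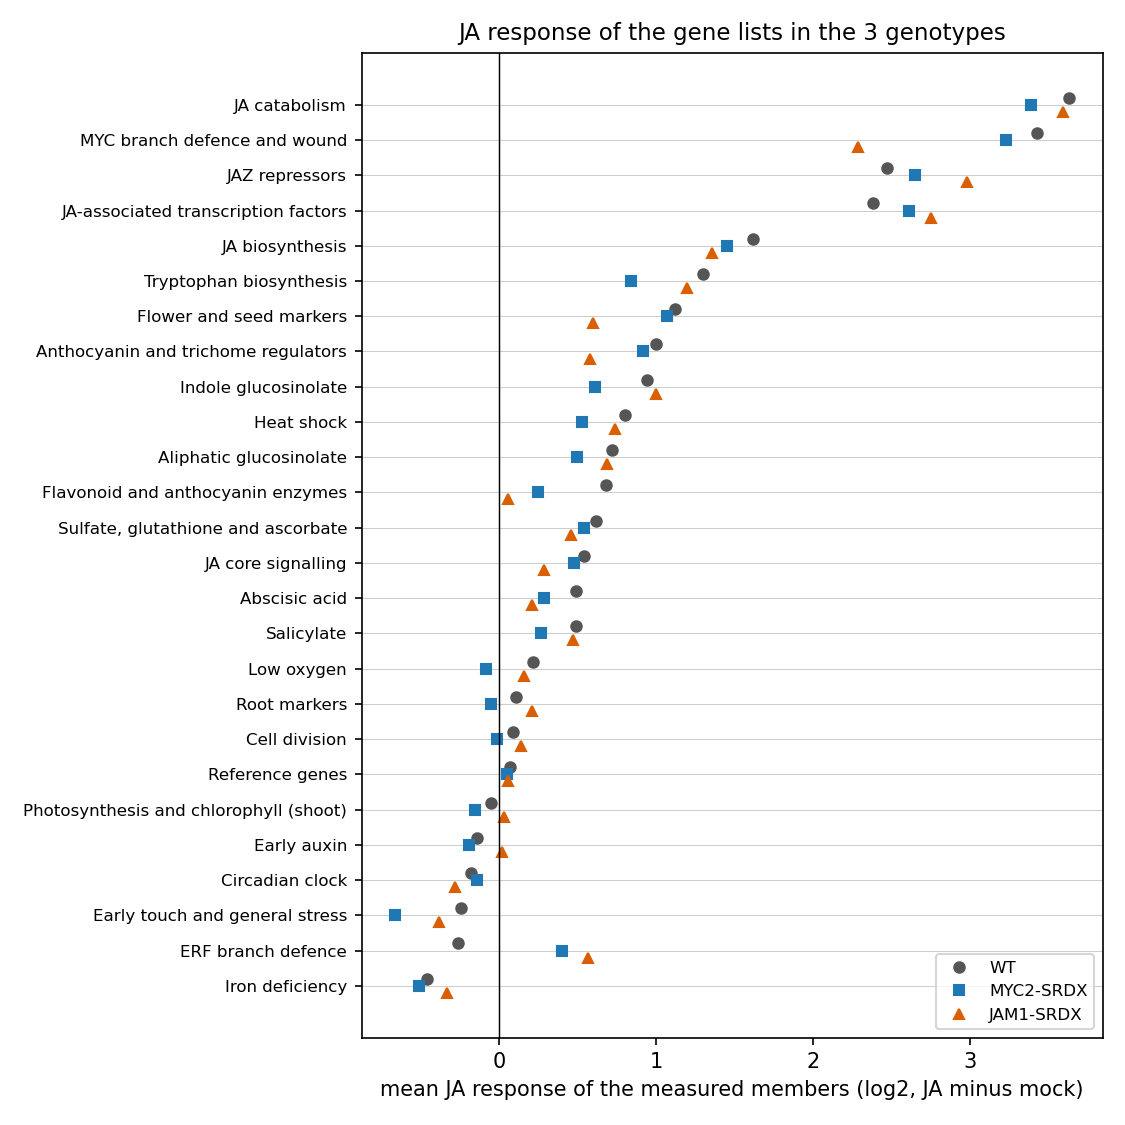
Mean JA response of the measured members of each fixed gene list in the 3 genotypes, as log2 of JA minus mock; each point is 1 list in 1 genotype. JA catabolism stood at 3.63, 3.39 and 3.59 in wild type, MYC2-SRDX and JAM1-SRDX, while ERF branch defence stood at -0.26, 0.40 and 0.57 (0.21 on the slide that held both JAM1-SRDX groups).

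In MYC2-SRDX seedlings JA still raised jasmonate genes, many of them from a lower mock level. TPS04 rose at least 30.3-fold from a level not well above background on any mock array (adjusted p = 7.23e-09), and JAZ13 at least 14.9-fold (adjusted p = 3.3e-10). MYC2 rose by 1.12 ± 0.11 (adjusted p = 8.81e-08), JAM1 by 1.75 ± 0.15 (adjusted p = 2.37e-08), LOX3 by 3.09 ± 0.18 (adjusted p = 7.9e-11) and JOX4 by 6.02 ± 0.60 (adjusted p = 1.4e-07). NCED3, the rate-setting enzyme of abscisic acid synthesis, rose by 2.33 ± 0.19 (adjusted p = 9.14e-09). TCH4, a wall enzyme raised by touch, fell by 1.56 ± 0.30 (adjusted p = 0.000416). BSMT1, which makes methyl salicylate, was well above background on 1 JA array and no mock array and did not pass (adjusted p = 0.415). In total 2916 genes rose and 3579 fell, with 543 rising and 258 falling at least 2-fold. JA biosynthesis rose at 16 of 16 genes (16 over the list alone, camera adjusted p = 3.5e-17), JA catabolism at 8 of 9 (8 over the list alone, adjusted p = 3.96e-12) and the JAZ repressors at 11 of 12 (11 over the list alone, adjusted p = 9.26e-14). Tryptophan biosynthesis rose at 7 of 7 (7 over the list alone, adjusted p = 1.09e-08), and the MYC branch at 10 of 11 (10 over the list alone, adjusted p = 2.11e-12). Early touch and general stress genes fell at 9, rose at 1 and did not pass at 6 (9 and 1 over the list alone, adjusted p = 0.00128; adjusted p = 0.381 with an estimated correlation). Slide as a random block left 3628 of 6495 genes, and normexp left 2603; with the series matrix values 80.7% of the calls were higher in place of 44.9%.

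In JAM1-SRDX seedlings JA raised most jasmonate genes, but not the vegetative storage genes. JAZ8, well above background on 1 of the 4 mock arrays, rose by 6.50 ± 0.47 (adjusted p = 7.46e-10), and MAPKKK21, a kinase gene well above background on 2 mock arrays, by 6.03 ± 0.34 (adjusted p = 1.3e-11). MYC2 rose by 2.33 ± 0.11 (adjusted p = 6.53e-13), JAM1 by 1.59 ± 0.15 (adjusted p = 7.96e-08), CYP94B1 by 5.05 ± 0.18 (adjusted p = 2.29e-14) and LOX3 by 3.06 ± 0.18 (adjusted p = 3.66e-11). VSP1 and VSP2, the vegetative storage protein genes often used as jasmonate markers, stayed at 0.19 ± 0.24 (adjusted p = 0.605) and 0.09 ± 0.24 (adjusted p = 0.826). MYB75 also stayed (0.32 ± 0.23, adjusted p = 0.331), while ERF2, an activator of the ERF branch, rose by 2.24 ± 0.10 (adjusted p = 2.36e-13). In total 2317 genes rose and 3505 fell, with 579 rising and 136 falling at least 2-fold. JA biosynthesis rose at 15 of 16 genes (16 over the list alone, camera adjusted p = 3.24e-16; mean 1.36, and 1.38 on the shared slide). JA catabolism rose at 9 of 9 (9 over the list alone, adjusted p = 1.02e-14; mean 3.59, and 3.26 on that slide). Aliphatic glucosinolate genes rose at 12 and fell at 1 of 14 (13 and 1 over the list alone, adjusted p = 2.72e-10; mean 0.69, and 0.64 on that slide). The MYC branch rose at 8 of 11 (8 over the list alone, adjusted p = 1.13e-07; adjusted p = 0.0642 with an estimated correlation; mean 2.29, and 1.52 on that slide). The slide that carried both groups held 1 array of each, and a fixed block for the slide rests on that pair alone. Among the 5822 genes 98.2% had the same direction there, but the pair also entered the calls; of 6093 genes called without that slide, a test chosen after seeing the data, 88.6% did. With the fixed block 2737 genes passed and after normexp 2244, and the share of higher calls went from 39.8% to 52.4% after normexp and to 62.8% with the series matrix values.

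Without JA, MYC2-SRDX seedlings held less RNA of many jasmonate genes than wild type. The MYC2 probe was 2.48 ± 0.11 higher in the line (adjusted p = 5.73e-12), while JAM1 did not pass (-0.41 ± 0.15, adjusted p = 0.0749), and the SUP probe was at least 1140-fold higher (adjusted p = 1.02e-19). TAT3 was at least 44.1-fold lower (adjusted p = 1.22e-06), TPS04 at least 16.7-fold (adjusted p = 1.38e-06) and UGT76E12, a glycosyltransferase, at least 20.6-fold (adjusted p = 1.38e-06). All 3 were not well above background on any array of the line. FAMT, a methyltransferase of the salicylate type, was lower (-4.55 ± 0.36, adjusted p = 2.02e-07). NATA1 was lower as well (-6.09 ± 0.72, adjusted p = 1.73e-05), which was well above background on 1 of the 4 arrays of the line. The early stress regulators WRKY33 (1.31 ± 0.21, adjusted p = 0.000246) and ZAT10 (1.12 ± 0.17, adjusted p = 0.000168) were higher. So were CYP81F2, which modifies indole glucosinolates (1.33 ± 0.21, adjusted p = 0.000283), and the phloem lectin-like gene PP2-B13 (2.28 ± 0.33, adjusted p = 9.37e-05). In total 1949 genes were higher and 1405 lower, 113 and 133 of them at least 2-fold. The 3354 genes became 374 with the slide as a random block, 648 after normexp and 2073 without MYC2-SRDX mock replicate 2, and with the series matrix values 89.3% of the calls were higher in place of 58.1%. Over probes well above background on all 24 arrays 162 genes changed at least 2-fold in place of 246.

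By gene list, aliphatic glucosinolate genes were lower at 13 of 14 in MYC2-SRDX mock (14 over the list alone, camera adjusted p = 2.32e-17), the 1 list call of the line comparisons kept with an estimated correlation (adjusted p = 0.0377). JA biosynthesis was lower at 9 of 16 (11 over the list alone, adjusted p = 1.33e-08; adjusted p = 0.0986 with an estimated correlation), with AOC1 at -1.53 ± 0.20 (adjusted p = 4.24e-05). JA catabolism was lower at 6 of 9 (7 lower and 1 higher over the list alone, adjusted p = 1.87e-06; adjusted p = 0.106 with an estimated correlation), with CYP94B3 at -1.86 ± 0.18 (adjusted p = 1.88e-06). The MYC branch was lower at 7 of 11 (7 over the list alone, adjusted p = 1.22e-08; adjusted p = 0.0986 with an estimated correlation). Of the JAZ repressors 7 were lower and 1 higher (the same over the list alone, adjusted p = 0.00035; adjusted p = 0.268 with an estimated correlation). JAZ8, well above background on 2 of 4 arrays of the line, stood at -3.90 ± 0.47 (adjusted p = 1.85e-05), while JAZ1 did not pass (-0.28 ± 0.20, adjusted p = 0.346). ERF branch defence was lower at 5 and higher at 1 of 11 (8 and 1 over the list alone, adjusted p = 0.000363; adjusted p = 0.216 with an estimated correlation). Early touch and general stress was higher at 14 of 16 (15 over the list alone, adjusted p = 7.64e-11; adjusted p = 0.0986 with an estimated correlation).

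After JA, MYC2-SRDX seedlings stayed below wild type at many of the genes that JA raises. The MYC2 probe was 1.00 ± 0.11 higher in the line (adjusted p = 8.25e-07), and the SUP probe at least 2260-fold higher (adjusted p = 2.82e-20). BSMT1, well above background on 1 of 4 arrays of the line, was lower (-6.60 ± 0.92, adjusted p = 1.87e-05). Lower too were TAT3 (-5.41 ± 0.65, adjusted p = 3.26e-06) and FAMT (-4.83 ± 0.36, adjusted p = 5.5e-09). So were the jasmonate genes CYP94B3 (-4.05 ± 0.18, adjusted p = 4.43e-12), CYP94B1 (-2.59 ± 0.18, adjusted p = 2.59e-09) and JMT (-2.60 ± 0.14, adjusted p = 7.97e-11). RD20 was lower (-2.74 ± 0.23, adjusted p = 3.44e-08), ORA59 was higher (1.16 ± 0.11, adjusted p = 1.83e-07), and LOX3 was level (-0.05 ± 0.18, adjusted p = 0.864). In total 3251 genes were higher and 2592 lower, 124 and 345 of them at least 2-fold. Tryptophan biosynthesis was lower at 7 of 7 (7 over the list alone, camera adjusted p = 1.09e-09; adjusted p = 0.0527 with an estimated correlation), with IGPS, the indole-3-glycerol phosphate synthase, at -0.94 ± 0.08 (adjusted p = 2.72e-08). Indole glucosinolate genes were lower at 9 and higher at 2 of 13 (the same over the list alone, adjusted p = 4.2e-06; adjusted p = 0.064 with an estimated correlation), with CYP83B1 at -1.27 ± 0.09 (adjusted p = 2.14e-09) and CYP81F2 at 1.64 ± 0.21 (adjusted p = 8.41e-06). Flavonoid and anthocyanin enzymes were lower at 12 of 14 (12 over the list alone, adjusted p = 4.51e-07; adjusted p = 0.064 with an estimated correlation). Low oxygen genes were lower at 10 of 10 (10 over the list alone, adjusted p = 9.8e-07; adjusted p = 0.205 with an estimated correlation), with the alcohol dehydrogenase ADH1 at -1.10 ± 0.20 (adjusted p = 0.000298). Fitting the slide as a random block gave 2600 genes in place of 5843, normexp 1693 and the series matrix values 10140. The share of higher calls, 55.6%, was 43.9% after normexp and 93.3% with the series matrix values.

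Without JA, JAM1-SRDX seedlings held less RNA of JAZ and jasmonate-breakdown genes and of trichome regulators. The JAM1 probe was 2.41 ± 0.15 higher in the line (adjusted p = 2.13e-09), MYC2 was lower (-0.59 ± 0.11, adjusted p = 0.000502), and the SUP probe was at least 803-fold higher (adjusted p = 2.36e-19). JOX4 was lower (-5.09 ± 0.60, adjusted p = 5.32e-06), as were JAZ10 (-2.31 ± 0.25, adjusted p = 2.37e-06), JAZ1 (-1.33 ± 0.20, adjusted p = 5.92e-05) and, well above background on 1 of 4 arrays of the line, JAZ8 (-4.55 ± 0.47, adjusted p = 1.05e-06). GL1, the MYB factor that starts trichomes, was well above background on 1 of 4 arrays of the line and lower (-4.05 ± 0.54, adjusted p = 1.93e-05). GL2, which acts after it, was lower too (-1.63 ± 0.10, adjusted p = 1.12e-09). TTG1, the WD40 partner of GL1, did not pass (0.09 ± 0.03, adjusted p = 0.07). VSP1 (1.36 ± 0.24, adjusted p = 0.000297) and VSP2 (1.23 ± 0.24, adjusted p = 0.00097) were higher. LOX3 (-1.18 ± 0.18, adjusted p = 9.91e-05) and ANAC019, a NAC factor (-3.05 ± 0.40, adjusted p = 1.53e-05), were lower. The stress factor ERF104 was higher (1.3 ± 0.12, adjusted p = 1.57e-07). In total 2581 genes were higher and 2229 lower, 427 and 184 of them at least 2-fold. JA catabolism was lower at 7 of 9 (9 over the list alone, camera adjusted p = 1.89e-06; adjusted p = 0.262 with an estimated correlation), and the JAZ repressors at 9 of 12 (10 lower and 1 higher over the list alone, adjusted p = 1.48e-06; adjusted p = 0.297 with an estimated correlation). JA biosynthesis was lower at 11 and higher at 2 of 16 (12 and 2 over the list alone, adjusted p = 4.86e-05; adjusted p = 0.301 with an estimated correlation). Anthocyanin and trichome regulators were lower at 5 of 10 (5 lower and 1 higher over the list alone, adjusted p = 0.000308; adjusted p = 0.262 with an estimated correlation), and the MYC branch had 3 higher and 2 lower (3 and 3 over the list alone, adjusted p = 0.631). After normexp the calls of GL1 (-2.12, adjusted p = 0.0612) and of the trichome regulators (-0.59, adjusted p = 0.075) were lost, and 824 genes (47.3% of them higher in place of 53.7%) passed in place of 4810, against 1653 with the slide as a random block and 2367 with the series matrix values (80.1% higher). Over probes well above background on all 24 arrays 332 genes changed at least 2-fold in place of 611.

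After JA, JAM1-SRDX seedlings were below wild type at several jasmonate, anthocyanin and trichome genes and above it at ORA59 and ERF2, activators of the ERF branch. The JAM1 probe was 2 ± 0.15 higher in the line (adjusted p = 8.49e-09), MYC2 (-0.86 ± 0.11, adjusted p = 4.36e-06) and JAM2 (-0.65 ± 0.09, adjusted p = 1.76e-05) were lower, and the SUP probe was at least 2060-fold higher (adjusted p = 3.47e-20). JMT (-3.37 ± 0.14, adjusted p = 9.53e-13), JOX4 (-3.78 ± 0.60, adjusted p = 7.1e-05), CYP94B3 (-2.60 ± 0.18, adjusted p = 2.07e-09), JAZ3 (-1.61 ± 0.13, adjusted p = 1.44e-08) and JAZ12 (-1.06 ± 0.06, adjusted p = 3.81e-10) were lower. MYB75 (-2.78 ± 0.23, adjusted p = 2.13e-08), the anthocyanin acyltransferase 5MAT (-2.16 ± 0.32, adjusted p = 3.06e-05) and BAM5, a beta-amylase (-4.67 ± 0.37, adjusted p = 1.02e-08), were lower as well. ORA59 (1.75 ± 0.11, adjusted p = 5.56e-10), ERF2 (0.88 ± 0.10, adjusted p = 7.68e-07), ERF6 (1.36 ± 0.20, adjusted p = 3.74e-05) and WRKY33 (1.44 ± 0.21, adjusted p = 2.19e-05) were higher. TAT3 did not pass (-0.61 ± 0.65, adjusted p = 0.517). In total 3324 genes were higher and 3037 lower, 304 and 315 of them at least 2-fold. JA biosynthesis was lower at 13 and higher at 1 of 16 (14 and 1 over the list alone, camera adjusted p = 7.09e-09; adjusted p = 0.127 with an estimated correlation). The MYC branch was lower at 7 of 11 (7 over the list alone, adjusted p = 3.52e-05; adjusted p = 0.265 with an estimated correlation), and anthocyanin and trichome regulators at 6 of 10 (6 over the list alone, adjusted p = 1.53e-05; adjusted p = 0.127 with an estimated correlation). ERF branch defence had 3 higher, 1 lower and 7 not passed (3 and 1 over the list alone, adjusted p = 0.238), with a median of -0.02 and a mean of 0.29. With the slide as a random block 2983 genes passed in place of 6361, after normexp 1656 (45.7% of them higher in place of 52.3%) and with the series matrix values 3601 (75.4% higher).

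The JA responses of MYC2-SRDX and wild type differed at 537 genes, 184 with a higher and 353 with a lower response in the line. Regrouping the arrays left chance open for this count. The MYC2 probe, whose signal from the transgene is not known, rose less in the line (difference -1.49 ± 0.15, adjusted p = 6.68e-06), as did CYP94B3 (-2.19 ± 0.26, adjusted p = 3.71e-05), CYP94B1 (-2.06 ± 0.26, adjusted p = 8.05e-05) and JAR1, which makes the active jasmonate conjugate (-0.94 ± 0.06, adjusted p = 8.61e-09). XERICO, a RING protein linked to abscisic acid (2.24 ± 0.19, adjusted p = 4.02e-07), responded more strongly in the line. ORA59, which fell in wild type, rose in the line (difference 1.31 ± 0.16, adjusted p = 4.86e-05). JAZ1 responded alike (0.05 ± 0.28, adjusted p = 0.965). Tryptophan biosynthesis had a lower response at 5 of 7 genes (5 over the list alone, camera adjusted p = 4.93e-09; adjusted p = 0.121 with an estimated correlation), and indole glucosinolate at 3 of 13 (7 over the list alone, adjusted p = 9.77e-07; adjusted p = 0.121 with an estimated correlation). With the slide as a random block 57 genes passed, after normexp 113, with the series matrix values 107 (47.7% of them higher in place of 34.3%), and without the 4 arrays of the shared slide, a setting chosen after seeing the data, 912.

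The JA responses of JAM1-SRDX and wild type differed at 776 genes, 210 with a higher and 566 with a lower response in the line. Regrouping the arrays did not exclude chance for this count, as 5 of 100 regroupings called as many genes. VSP1 (-2.34 ± 0.33, adjusted p = 0.00023) and VSP2 (-2.30 ± 0.34, adjusted p = 0.000411) responded less in the line. The same held for JAR1 (-1 ± 0.06, adjusted p = 2.79e-09) and CYP94B3 (-1.96 ± 0.26, adjusted p = 0.000111). The VSP1 and VSP2 probes read alike, at 1.12 and 1.34 in wild-type mock and 2.49 and 2.57 in JAM1-SRDX mock. With no probe positions at hand, whether they are separate readings is not known. ERF2 responded more strongly (1.22 ± 0.14, adjusted p = 2.52e-05), and ORA59, which fell in wild type, rose in the line (difference 1.53 ± 0.16, adjusted p = 1.54e-05). MYC2 (-0.27 ± 0.15, adjusted p = 0.426) and JAM1 (-0.41 ± 0.22, adjusted p = 0.399) did not pass. The MYC branch had a lower response at 6 of 11 genes (6 over the list alone, camera adjusted p = 3.53e-05; adjusted p = 0.477 with an estimated correlation), and JA biosynthesis at 3 of 16 (7 over the list alone, adjusted p = 0.000312; adjusted p = 0.477 with an estimated correlation). Fewer genes passed with the slide as a random block (140), after normexp (77, of them 16.9% higher in place of 27.1%) and with the series matrix values (312).

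Set against each other without JA, JAM1-SRDX held more RNA of MYC-branch genes than MYC2-SRDX. The MYC2 probe was lower in JAM1-SRDX (-3.07 ± 0.11, adjusted p = 1.73e-13) and the JAM1 probe higher (2.82 ± 0.15, adjusted p = 4.86e-10). TAT3 was at least 28.4-fold higher in JAM1-SRDX (adjusted p = 9.83e-07), and VSP2 (2.51 ± 0.24, adjusted p = 5.72e-07) and the lipoxygenase LOX2 (1.27 ± 0.13, adjusted p = 8.05e-07) were higher. MYB23, a trichome MYB related to GL1 (-2.87 ± 0.27, adjusted p = 5.23e-07), and JAZ1 (-1.05 ± 0.20, adjusted p = 0.000719) were lower. In total 2352 genes were higher and 2452 lower, 331 and 151 of them at least 2-fold. The MYC branch was higher at 7 and lower at 1 of 11 (the same over the list alone, camera adjusted p = 3.07e-05; adjusted p = 0.543 with an estimated correlation), and aliphatic glucosinolate genes higher at 10 of 14 (11 over the list alone, adjusted p = 1.7e-07; adjusted p = 0.543 with an estimated correlation). With the slide as a random block 1513 genes passed in place of 4804, after normexp 906 and with the series matrix values 2061. Over probes well above background on all 24 arrays 269 genes differed at least 2-fold in place of 482.

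Set against each other after JA, the lines differed at 7569 genes, 3515 higher and 4054 lower in JAM1-SRDX. The MYC2 probe was lower in JAM1-SRDX (-1.86 ± 0.11, adjusted p = 1.65e-10) and the JAM1 probe higher (2.66 ± 0.15, adjusted p = 1.65e-10). TAT3 (4.80 ± 0.65, adjusted p = 1.11e-05), FAMT (4.60 ± 0.36, adjusted p = 9.21e-09) and CYP94B3 (1.45 ± 0.18, adjusted p = 4.57e-06) were higher. XERICO (-3.43 ± 0.13, adjusted p = 6.08e-13), NCED3 (-3.06 ± 0.19, adjusted p = 4.8e-10) and TGG2, a myrosinase (-2.97 ± 0.24, adjusted p = 1.77e-08), were lower. Of the 25 lists tested 7 were called higher and 1 lower, 0 of them with an estimated correlation. The largest mean among those called was ERF branch defence at 1.02 (adjusted p = 0.00584; adjusted p = 0.512 with an estimated correlation), while the MYC branch, at 1.24, did not pass (adjusted p = 0.116). Aliphatic glucosinolate genes were higher at 12 and lower at 1 of 14 (the same over the list alone, camera adjusted p = 5.25e-08; adjusted p = 0.317 with an estimated correlation; mean 0.62, and 0.61 on the shared slide). Anthocyanin and trichome regulators were lower at 5 of 10 (5 over the list alone, adjusted p = 0.00385; adjusted p = 0.317 with an estimated correlation; mean -0.85, and -0.98 on that slide), a call lost after normexp (-0.09, adjusted p = 0.358). The JA responses of the lines differed at 1803 genes, 786 higher and 1017 lower in JAM1-SRDX. Among them were XERICO at -3.25 ± 0.19 (adjusted p = 2.76e-09), MYC2 at 1.22 ± 0.15 (adjusted p = 4.65e-05) and the lipoxygenase LOX4 at 1.85 ± 0.32 (adjusted p = 0.0011). Regrouping the arrays left chance open for the count of 1803 too. The slide shared by both lines held 1 JAM1-SRDX and 2 MYC2-SRDX arrays, on which alone a fixed block rests. There 98.7% of the 7569 genes had the same direction, but these arrays also entered the calls; of 6234 genes called without that slide, a test chosen after seeing the data, 87.7% did. With the fixed block 5913 genes passed, after normexp 2294 and with only the arrays compared 4600, and with the series matrix values 17.7% of the calls were higher in place of 46.4%. For the difference of responses, 466 genes passed with the slide as a random block, 242 after normexp (55% of them higher in place of 43.6%) and 614 with the series matrix values (24.9% higher).

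Most genes that JA raised in wild type also rose in each line, by less on average. Of the 797 genes raised at least 2-fold in wild type, 674 rose in MYC2-SRDX (median change 1.15) and 582 in JAM1-SRDX (median 1.24), against a wild-type median of 1.57. The response was smaller past the test at 191 and larger at 7 of them in MYC2-SRDX, and smaller at 196 and larger at 23 in JAM1-SRDX. These counts do not hold once the slide is a random block, which leaves 57 and 140 genes in all for the 2 differences of responses, against 113 and 77 after normexp. In 20 simulations with equal responses and no slide effect, 0 genes on average had a smaller response past the test. No response differed there, so that 0 was close to fixed and is no chance level for these counts. After JA 492 of the 797 were lower and 22 higher in MYC2-SRDX than in wild type, and 343 lower and 84 higher in JAM1-SRDX. The 797 genes were chosen on the same wild-type arrays, 1 slide per treatment, which by itself favours smaller responses and lower levels in the lines. With genes chosen on 1 part of the wild-type arrays and measured on the rest, MYC2-SRDX kept 75.9% of the wild-type mean response (range 68.9 to 85.9% over 6 choices), or 1.40 of 1.86. JAM1-SRDX kept 80.5% (71.9 to 91.9%), or 1.49 of 1.86. The held-out arrays lay on the same slides as those that chose the genes, so slide differences alone could lower both shares. Both ranges went with the wild-type arrays held out. Their mean response was 2.115 where replicates 1 and 2 chose the genes and 1.558 where 3 and 4 did. Wild-type mock arrays were uneven at JA biosynthesis: the SD of the list mean was 0.3, against 0.07 and 0.03 in MYC2-SRDX and JAM1-SRDX mock. At JA-associated transcription factors the SDs were alike (0.47, 0.49 and 0.44). The fit used 1 spread per gene for all groups. Of the 119 list calls in all comparisons, 23 held with the correlation between genes estimated from the data. They were JA biosynthesis, JA catabolism, JAZ repressors, JA-associated transcription factors, indole glucosinolate and tryptophan biosynthesis in the JA response of every genotype, the MYC branch in that of wild type and MYC2-SRDX, JA core signalling in that of MYC2-SRDX, aliphatic glucosinolate in that of JAM1-SRDX, and aliphatic glucosinolate in MYC2-SRDX mock.

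**Figure D3:**
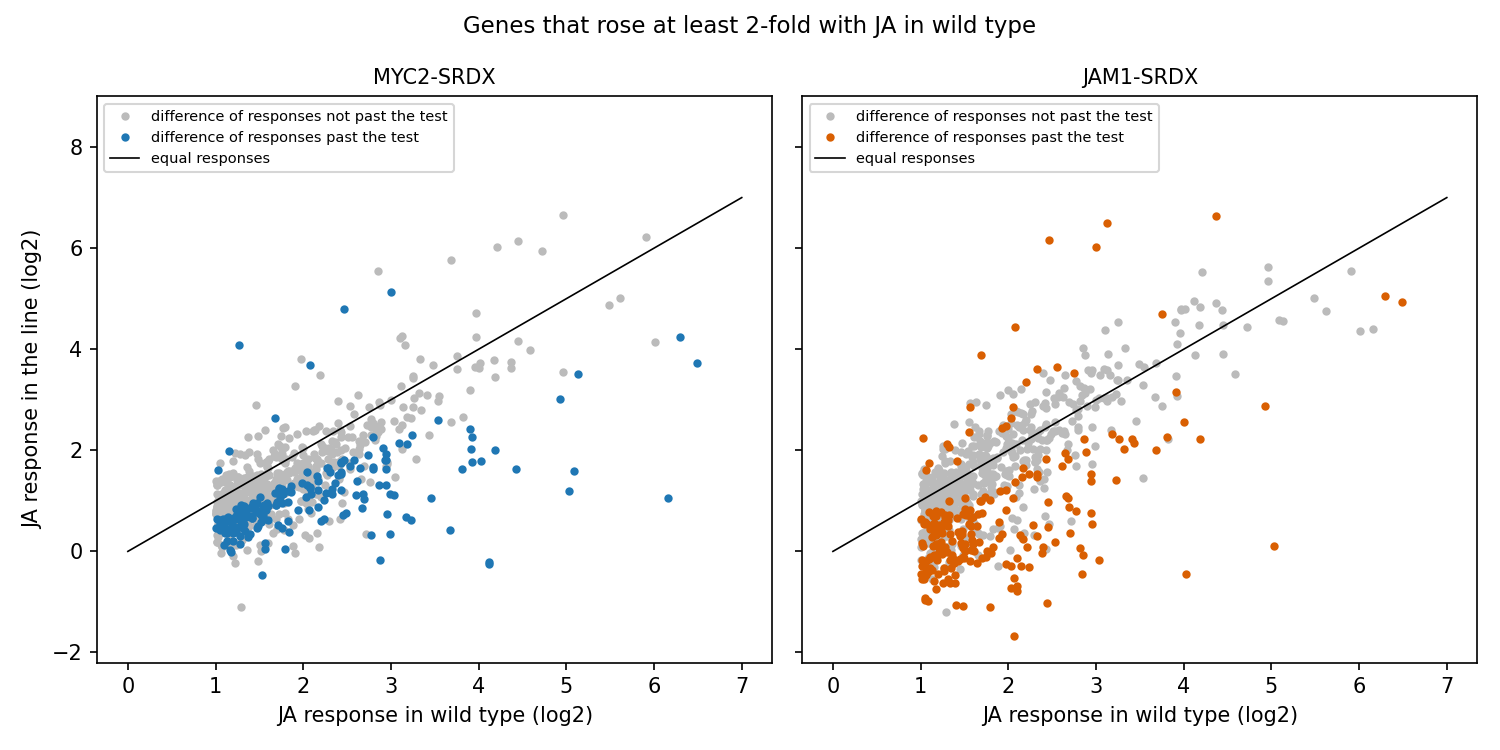
JA response in each line against that in wild type, both in log2 of JA minus mock, for the 797 genes that rose at least 2-fold in wild type; each point is 1 gene and the line marks equal responses. Coloured points differ past the test without a slide term: 191 below and 7 above for MYC2-SRDX, and 196 below and 23 above for JAM1-SRDX. A random block for the slide leaves 57 and 140 among all genes. The genes were chosen on the same wild-type arrays, which favours points below the line.

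The lines shared many of their differences from wild type. Without JA 1325 genes were called in the same direction in both, 767 higher and 558 lower, and 87 in opposite directions; independent lists would share 400.2 in direction, and simulations without any effect but with the shared wild-type arrays gave 0. The fold changes correlated at 0.5, where shared controls alone gave 0.505, but their covariance was 0.0652 against 0.00912 from the controls, a difference of 0.0561. With the wild-type arrays split between the lines 467 to 556 genes were shared, against 84.3 to 182.9 expected. After JA 2248 genes were shared in direction, 1271 higher and 977 lower, with 371 opposite, 915.7 expected and 0 simulated; the correlation was 0.486 against 0.501, and the covariance 0.0767 against 0.00901, a difference of 0.0677. Split controls gave 1192 to 1271 shared genes against 328 to 442.9 expected. All wild-type arrays of a treatment lay on 1 slide, so split controls still share that slide, and the simulations held no slide effect. They also held no effect in either line, so few genes could be called and an overlap of 0 was close to fixed. That 0 does not show what shared controls add to lists of real calls. CYP94B3 (-4.05 ± 0.18 and -2.60 ± 0.18) and JAZ12 (-0.79 ± 0.06 and -1.06 ± 0.06) were lower after JA in both lines, and ORA59 higher (1.16 ± 0.11 and 1.75 ± 0.11). The mean level of early touch and general stress genes was above wild type in both lines with and without JA. In mock it was 0.39 ± 0.16 in MYC2-SRDX and 0.36 ± 0.42 in JAM1-SRDX against -0.57 ± 0.25. After JA it was -0.27 ± 0.22 and -0.02 ± 0.17 against -0.81 ± 0.06. The cause was not tested. With the slide as a random block 149 genes were shared in mock and 875 after JA, and after normexp 198 and 570. The series matrix values gave 819 in mock, and leaving out the 4 arrays of the shared slide, chosen after seeing the data, gave 2217.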

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

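The splits of the arrays, the slide tests on the mock differences and the test for a lost segment around GL1 were written before their results were seen. The tests on SUP, the slide test on the JA rises, the slide test on JAM1-SRDX without the shared slide, the test for a missing GL1 gene and the splits with genotype means subtracted were chosen only after the result was seen.

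A gene or list was picked out where 1 replicate lay far from the other 3 of its group, which chance gives for about 1 in 20 groups. This held for 19 of 345 gene groups (5.5%), 9 of 156 list groups (5.8%) and 0 of 18 groups of array measures. In wild type the values were JAM1 2.80 (JA replicate 2), MYB21 -7.12 (mock 2), NATA1 1.52, ORA59 -1.74 and VSP2 3.96 (all JA 4), and ZIP7 -4.75 (mock 4). In MYC2-SRDX they were JAM3 0.69 and JAR1 2.04 (JA 3), CYP94B3 -1.61 (JA 2), MYB113 -2.97 (JA 1), SUP 4.73 (JA 4), and JOX3 -7.29, ANAC019 -3.31 and IGPS 2.13 (mock 1). In JAM1-SRDX they were JAM2 -0.85 and WOX5 -5.97 (mock 4), ERF2 -0.89 (mock 1) and 1.2 (JA 4), and NAC025 -5.27 (JA 4). Mean levels of lists stood apart for JA biosynthesis 0.98 (MYC2-SRDX mock 1), JA core signalling -0.52 (MYC2-SRDX mock 2), JA-associated transcription factors -1.67 and abscisic acid -0.20 (MYC2-SRDX JA 1). The others were the MYC branch 1.92 (wild-type JA 4), circadian clock -0.13 and heat shock -3.41 (JAM1-SRDX mock 4), cell division -0.87 (wild-type mock 2) and reference genes 3.04 (wild-type JA 1). By array, MYC2-SRDX mock 1, JAM1-SRDX mock 4 and wild-type JA 4 had 4 such values each and MYC2-SRDX JA 1 had 3.

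Differences in the JA response between genotypes were also picked out. The response of MYC2-SRDX and wild type differed at 537 genes, that of JAM1-SRDX and wild type at 776, and that of the 2 lines at 1803. In MYC2-SRDX minus wild type the genes were MYC2 -1.49, NAC025 -4.33, CYP94B3 -2.19, CYP94B1 -2.06, JAR1 -0.94, ORA59 1.31, XERICO 2.24, NCED3 1.47, IGPS -0.66, TSB2 -0.64 and GL3 -0.84. NAC025 was well above background on 0 arrays in 3 of the 4 groups, so -4.33 rests on background signal and is no measured size. After normexp NAC025 (adjusted p = 0.885), NCED3 (adjusted p = 0.885), IGPS (adjusted p = 0.224) and GL3 (adjusted p = 0.885) no longer passed, and TSB2 was lost with the series matrix values (adjusted p = 0.242). With the slide as a random block NCED3 (adjusted p = 0.149), IGPS (adjusted p = 0.092) and GL3 (adjusted p = 0.236) were lost. In JAM1-SRDX minus wild type they were AT5G38130 -4.92, THI2.1 -4.47, VSP1 -2.34, VSP2 -2.30, JMT -1.63, JAR1 -1, CYP94B3 -1.96, JAZ8 3.37, BHLH92 2.37, ORA59 1.53, ERF2 1.22, MYB75 -1.82, GL3 -1.05, RD20 -2.19, AP1 -2.76 and MAPKKK21 3.03. The values of AT5G38130 (0 arrays well above background in 3 groups), THI2.1 (0 in 2 groups) and AP1 (0 in both wild-type groups) rest on background signal too and are no measured sizes. Of the 4 JAM1-SRDX mock arrays JAZ8 was well above background on 1, and MAPKKK21 and BHLH92 on 2. GL3 was so on 3 of the 4 JAM1-SRDX JA arrays. The values of these genes rest in part on background signal. After normexp only VSP1, VSP2, JAR1, CYP94B3, ORA59 and ERF2 of these still passed, and the slide as a random block ended the calls of JAZ8 (adjusted p = 0.164), MYB75 (adjusted p = 0.107) and MAPKKK21 (adjusted p = 0.0532). Between the lines they were MYC2 1.22, XERICO -3.25, AP1 -3.18, LOX4 1.85, NAC025 4.08 and JMT -1.13. AP1 and NAC025 were well above background on 0 arrays of both MYC2-SRDX groups, so their values are no measured sizes. AP1 (adjusted p = 0.903), NAC025 (adjusted p = 0.616) and JMT (adjusted p = 0.933) were lost after normexp.

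Lists with a different mean response in MYC2-SRDX and wild type were JA biosynthesis -0.16, JA catabolism -0.24, ERF branch defence 0.66, flavonoid and anthocyanin enzymes -0.43, indole glucosinolate -0.33, aliphatic glucosinolate -0.22, tryptophan biosynthesis -0.46, early touch and general stress -0.42 and low oxygen -0.30. Several of these calls were lost when some single arrays were left out, at times with the mean almost unchanged. JA biosynthesis did not pass without wild-type mock 3 (-0.09, adjusted p = 0.11) or 4 (-0.07, adjusted p = 0.196). JA catabolism was lost without wild-type mock 3 (-0.14, adjusted p = 0.0515), wild-type mock 4 (-0.05, adjusted p = 0.12) or MYC2-SRDX mock 1 (-0.06, adjusted p = 0.0996). Early touch and general stress was lost without wild-type mock 4 (-0.31, adjusted p = 0.062). Low oxygen was lost without wild-type mock 3 (-0.25, adjusted p = 0.087) or 4 (-0.27, adjusted p = 0.0757), MYC2-SRDX mock 3 (-0.29, adjusted p = 0.0606) or 4 (-0.23, adjusted p = 0.11), wild-type JA 2 (-0.19, adjusted p = 0.163) or MYC2-SRDX JA 1 (-0.11, adjusted p = 0.491). ERF branch defence was lost without wild-type mock 1 (0.51, adjusted p = 0.134) or 2 (0.39, adjusted p = 0.296), MYC2-SRDX mock 2 (0.66, adjusted p = 0.0935) or 4 (0.57, adjusted p = 0.0925). It was also lost without wild-type JA 3 (0.63, adjusted p = 0.072) or 4 (0.67, adjusted p = 0.0587), or MYC2-SRDX JA 1 (0.69, adjusted p = 0.0946) or 3 (0.51, adjusted p = 0.112), and with replicate number as a block (0.66, adjusted p = 0.0685).

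For JAM1-SRDX and wild type the lists were JA biosynthesis -0.26, JA core signalling -0.25, the MYC branch -1.13, ERF branch defence 0.83 and flavonoid and anthocyanin enzymes -0.62, where ERF branch defence, whose JA response in JAM1-SRDX was 0.57 but 0.21 on the shared slide, was lost without wild-type mock 2 (0.55, adjusted p = 0.119) or JAM1-SRDX mock 3 (0.58, adjusted p = 0.0565). Between the lines they were the MYC branch -0.94, indole glucosinolate 0.39, aliphatic glucosinolate 0.20, tryptophan biosynthesis 0.36 and photosynthesis and chlorophyll 0.18. Aliphatic glucosinolate was lost without JAM1-SRDX mock 4 (0.11, adjusted p = 0.146), MYC2-SRDX JA 1 (0.16, adjusted p = 0.086) or JAM1-SRDX JA 3 (0.17, adjusted p = 0.0832). Photosynthesis and chlorophyll was lost without MYC2-SRDX mock 4 (0.17, adjusted p = 0.0622), JAM1-SRDX mock 2 (0.17, adjusted p = 0.0629) or 4 (0.15, adjusted p = 0.135), MYC2-SRDX JA 2 (0.14, adjusted p = 0.107) or 3 (0.14, adjusted p = 0.112), or JAM1-SRDX JA 1 (0.14, adjusted p = 0.118) or 4 (0.18, adjusted p = 0.0599). The MYC branch between the lines was lost after normexp (-0.12, adjusted p = 0.124). None of the list differences between responses held with an estimated correlation. Probes matched to no locus were picked out as data left unused: of 4400 tested, 1241 were called in the JA response of wild type and 1132 in JAM1-SRDX against wild type in mock.

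Chance was tested by regrouping the arrays of each comparison of 2 groups into all 35 splits and refitting, where 1 split, the real one, gave as many calls in each case. The highest other split called 0 genes for JA in wild type (real 7088), 197 in MYC2-SRDX (6495), 1082 in JAM1-SRDX (5822), 1 for MYC2-SRDX against wild type in mock (3354) and 153 after JA (5843). It called 16 for JAM1-SRDX against wild type in mock (4810), 8 after JA (6361), 8 for the lines in mock (4804) and 205 after JA (7569). Chance differences between single arrays were excluded for 7 of these, all but the JA responses of MYC2-SRDX and JAM1-SRDX. In all 7 but the lines after JA, the 2 groups shared no slide. A slide difference would also make the real split the largest there, and regrouping does not exclude it. In the JA responses of MYC2-SRDX and JAM1-SRDX the same-numbered arrays of mock and JA were correlated. Only 8 splits part all 4 pairs, too few for a share under 0.05. Among the 8 the highest other split called 1 gene in MYC2-SRDX and 3 in JAM1-SRDX, so the 197 and 1082 came from splits that do not part the pairs. Parting the pairs did not remove the 153 genes of MYC2-SRDX against wild type after JA. For the differences of responses 4 of 100 regroupings called as many genes for MYC2-SRDX (highest 3947), 5 of 100 for JAM1-SRDX (highest 3984) and 3 of 100 between the lines (highest 2313), so that regrouping did not exclude chance for JAM1-SRDX. Those regroupings mix whole genotypes. With genotype means subtracted 1 of 100, the real one, was as large in each case, and the highest others were 35, 382 and 316. All of these regroupings moved mock and JA arrays separately, so they broke the same-numbered pairs that were correlated in both lines. Chance is therefore left open for each difference of responses.

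A SUP probe was bright in both lines and dark in wild type. If it reads the SRDX motif of the transgenes, it should follow the probe of the fused gene, and the largest gap between their JA changes was 0.11 (1.11 and 1.12 in MYC2-SRDX, 1.49 and 1.59 in JAM1-SRDX). That is consistent with a signal from the transgenes. Activity of the SUP gene itself could not be told apart, since the second SUP probe, at most 0.02 above wild type, was well above background on 0 arrays.

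The groups compared lay mostly on different slides. Slide differences as the whole of the JA rises of wild type are excluded by MYC2-SRDX on other slides, where the same genes rose by a median of 1.15 (JAM1-SRDX 1.24, wild type 1.57), and by the arrays within the shared slide, where they rose by 1.23; 87% were higher in both lines. Slide differences as the whole of the mock differences are excluded for MYC2-SRDX because 94.2% of its calls kept their sign after JA on other slides, with 2152 of 2171 genes called in both treatments going the same way. For JAM1-SRDX 92.1% did, but 1 array of each of its groups lay on the shared slide. Without that slide 91.3% kept their sign on other slides, with 3720 of 3823 going the same way, which excludes it there too. What part of each gene's difference came from the slide stays open, as wild-type mock, wild-type JA and MYC2-SRDX mock each filled a slide of their own.

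GL1 was low in JAM1-SRDX with and without JA. A lost or foreign segment around the gene was expected to change many of its neighbours. Of the 20 nearest measured genes 1 was called and changed 2-fold in both treatments, against 1.23% of all genes. In mock 8 of the 20 were called, against 23.6% of all genes, with a largest difference of 1.83. Both counts are above the share of all genes but rest on few neighbours. A loss confined to GL1, or a segment with few expression differences, would leave most neighbours unchanged, so the test cannot decide. Whether the gene is missing could not be told, since its probe was well above background on 3 of 8 arrays of the line. Repression by the transgene was not tested.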

How the results depend on the processing

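Block by replicate within each genotype and the fits without the 4 arrays of the shared slide were chosen only after the result was seen; all other settings were fixed before the data were examined. No call on a named gene turned its direction, and no call on a list did in the settings where lists were tested, though the majority direction of the genes called did where shares below cross 50%. The list tests were not run with the slide as a fixed or random block, the scan day as a block, the series matrix values or the replicate block within each genotype, so whether list calls hold there is not known. On the shared slide, where JAM1-SRDX has 1 array per treatment, 2 list means of its JA response that carried no call turned, iron deficiency from -0.33 to 0.23 and flower and seed markers from 0.6 to -0.09. The transgene differences stayed at 2.48 to 2.63 (MYC2) and 2.29 to 2.50 (JAM1) over the settings; the cause of the changes below was not tested. After normexp the counts of genes called were 3089 of 7088 for JA in wild type, 2603 of 6495 in MYC2-SRDX and 2244 of 5822 in JAM1-SRDX. Against wild type they were 648 of 3354 and 1693 of 5843 (MYC2-SRDX, mock and JA) and 824 of 4810 and 1656 of 6361 (JAM1-SRDX), between the lines 906 of 4804 and 2294 of 7569, and for differences of responses 113 of 537, 77 of 776 and 242 of 1803 (MYC2-SRDX, JAM1-SRDX, between the lines). The overlaps were 198 of 1325 and 570 of 2248, and JAM1-SRDX kept 94.1% of the JA response in place of 80.5%. With the series matrix values JA changed 3691 genes in wild type and 2603 in JAM1-SRDX; 10140 differed in MYC2-SRDX after JA, 2367 and 3601 in JAM1-SRDX without and with JA, and 2061 between the lines in mock. The differences of responses were 107, 312 and 614, the mock overlap 819, and MYC2-SRDX kept 83% in place of 75.9%. With the slide as a random block the counts were 3506 and 3628 (JA in wild type and MYC2-SRDX), 374 and 2600 (MYC2-SRDX against wild type), 1653 and 2983 (JAM1-SRDX against wild type), 1513 (lines in mock), 57, 140 and 466 (differences of responses), and 149 and 875 (overlaps). As a fixed block the slide left 2737 genes for JA in JAM1-SRDX, and with only the arrays compared 4600 differed between the lines after JA. Without the 4 arrays of the shared slide 5229 genes differed in MYC2-SRDX mock, 912 in its response, and 2217 were shared in mock. Leaving out 1 array gave 2073 to 2717 genes for MYC2-SRDX mock, lowest without its mock replicate 2. With an estimated correlation 23 of 119 list calls were kept. The share of calls that were higher moved by over 10 points after normexp in JA for JAM1-SRDX (39.8 to 52.4%), MYC2-SRDX after JA (55.6 to 43.9%), and the responses of JAM1-SRDX against wild type (27.1 to 16.9%) and MYC2-SRDX (43.6 to 55%). With the series matrix values it moved for JA in wild type (41.6 to 59.3%), MYC2-SRDX (44.9 to 80.7%) and JAM1-SRDX (39.8 to 62.8%), for MYC2-SRDX in mock (58.1 to 89.3%) and after JA (55.6 to 93.3%), and for JAM1-SRDX in mock (53.7 to 80.1%) and after JA (52.3 to 75.4%). It also moved for the response of MYC2-SRDX (34.3 to 47.7%), the lines after JA (46.4 to 17.7%) and their responses (43.6 to 24.9%). Smaller moves crossed 50% for JAM1-SRDX in mock (53.7 to 45.8% with quantile normalization and 47.3% after normexp) and after JA (52.3 to 45.7% after normexp), and for JA in JAM1-SRDX with the slide as a fixed block (39.8 to 51.7%). Between the lines the share in mock went from 49 to 53.3% after normexp and 53.1% with the slide as a random block, and after JA from 46.4 to 51.5% after normexp. The median over all genes shifted by over 0.1 with those values for JA in MYC2-SRDX (0.167), MYC2-SRDX in mock (0.145) and after JA (0.257), JAM1-SRDX after JA (0.106), the MYC2-SRDX response (0.112) and the lines after JA (-0.151), and after normexp for the lines after JA (0.101), so small fold changes of both signs there depend on the scaling. The replicate number as a block gave 7141, 6513 and 5892 genes for JA in the 3 genotypes and 524, 804 and 1866 for the differences of responses; it ended the ERF branch call in MYC2-SRDX minus wild type and changed no other call. Within each genotype it gave 7901, 7223 and 6789, and 718, 1048 and 2566. Same-numbered arrays of other pairs of groups did not all correlate above 0.1. Of the calls on named genes 2857 stayed, 77 were lost and 8 gained over the settings, and of those on lists, over the settings where these were tested, 2812, 143 and 45; over left-out arrays they were 2219, 3 and 2, and 2878, 58 and 64. The 3 lost over left-out arrays were all JAM2 in the JA response of JAM1-SRDX, without mock replicate 4 (adjusted p = 0.0715) or JA replicate 2 (adjusted p = 0.106) or 3 (adjusted p = 0.0875). Of the 77 lost calls 55 were lost after normexp and 14 with the slide as a random block. The 14 were JAZ10, CBF1, VSP2 and NCED3 in MYC2-SRDX mock, DFR in MYC2-SRDX after JA, JAM2 in JAM1-SRDX mock, LDOX in JAM1-SRDX after JA and JAZ10 between the lines in mock, with NCED3, IGPS and GL3 in the response of MYC2-SRDX and JAZ8, MYB75 and MAPKKK21 in that of JAM1-SRDX.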

Other observations

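The probes without a locus and the values by replicate below were looked at only after the result was seen.

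The JAM1-SRDX replicates differed in the level of the fused gene. The JAM1 probe read 3.66, 3.06, 2.83 and 3.63 in mock replicates 1 to 4 and 5.20, 4.48, 4.75 and 5.11 after JA. The SUP probe read 3.04, 2.45, 2.15 and 3.04 in mock and 4.66, 3.68, 3.87 and 4.41 after JA. GL1 read -8.78, -7.60, -6.17 and -6.79 in mock and -8.18, -5.81, -5.96 and -8.98 after JA, with 1 and 2 of these arrays well above background. No test was made on these values.

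Of the 4400 tested probes without a locus, 1241 changed with JA in wild type (750 higher, 491 lower), 1096 in MYC2-SRDX and 747 in JAM1-SRDX. In mock 1132 differed in JAM1-SRDX (833 higher, 299 lower) and 334 in MYC2-SRDX. These probes await a match to a current genome.

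Several JA-raised genes were smaller in their response in both lines, among them CYP94B3 (-2.19 and -1.96) and JAR1 (-0.94 and -1), while ORA59, which fell in wild type, rose in both lines (difference 1.31 and 1.53). One reading of the smaller responses is that JAM1 and MYC2 bind some of the same promoters, so that either fusion may repress them. It does not account for the rise of ORA59. MYC2 itself was also lower in JAM1-SRDX than in wild type, at 0.75 ± 0.21 against 1.34 ± 0.24 in mock, and its part was not tested. The slide test excludes slide differences as the whole of the mock differences (94.2 and, without the shared slide, 91.3% of calls kept their sign), but not as a part of each gene's value. Binding of both fusions at the CYP94B3 and JAR1 promoters, by chromatin precipitation in the same lines, would test whether they share these promoters. Arrays of the groups compared placed together on the same slides would settle the slide's part.

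VSP1 and VSP2 went the other way in mock: both were higher than wild type in JAM1-SRDX and VSP2 was lower in MYC2-SRDX (-1.28 ± 0.24, adjusted p = 0.00117; adjusted p = 0.0862 with the slide as a random block). JA did not move either gene past the test in JAM1-SRDX, and after JA both mean levels lay below wild type. VSP1 stood at 2.67 ± 0.27 against 3.65 ± 0.18 and VSP2 at 2.66 ± 0.26 against 3.73 ± 0.15. A possible explanation is that the fusion of JAM1 acts on a repressor of these genes in mock seedlings, but the slide could add to the mock difference. With the shared slide left out 91.3% of all JAM1-SRDX mock calls kept their sign on other slides. In the full fit VSP1 and VSP2 did not keep theirs. A time course of VSP2 after JA in all 3 genotypes on shared slides would show the slide's part in the mock difference. It would not show whether the fusion acts on a repressor.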
